A study of Rattus norvegicus with 9 samples.

How the data were processed

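RNA from rat PASMCs was measured in 9 samples, 3 each in normoxia, in hypoxia and in hypoxia with quercetin, on 1-colour Agilent whole-genome rat arrays. Per the labels' protocols, hypoxic cells were held in an airtight chamber with 1% oxygen and 5% carbon dioxide and control cells in a normoxic incubator at 37 °C. Cells went 24 h without serum and then received quercetin or 0.1% DMSO, the vehicle, for 24 h in medium with 10% serum. The quercetin dose is not given in the sources used here. The labels describe labelling with a microRNA kit, while the scanner output names a gene expression protocol and holds probes for messenger RNA, so the labelling chemistry stays uncertain.

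Per the file headers, each array was scanned in 1 channel and quantified with Agilent Feature Extraction 10.7.3.1, which gave spot intensities with the local background already subtracted. The deposited value table holds log2 values whose columns share 1 distribution (median 5.71 in each), as after quantile normalization, and which correlated at 0.991 to 0.9998 across probes with the scanner intensities of the same array. How the authors made that table is not given in the sources used here. It served only as an alternative.

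From the scanner files, 1639 control spots were left out and spots marked as non-uniform or population outliers, 71 to 148 per array, were set missing. Saturated spots would have been kept, but there were none. The log2 of the processed intensity was taken, spots of 1 probe were averaged, and the 75th percentile over non-control probes was subtracted on each array. Over all non-control spots, before the log and before averaging by probe, the 75th percentile was 627 to 640 in normoxia, 439 to 462 in hypoxia and 450 to 504 with quercetin. The percentile subtracted was taken over probes, so it differs from these values. Probes well above background on all arrays of at least 1 group were kept, 26669 of 41012, or 65.0%. Of the 41012 probes, 18495 were named through their accession, 2903 by a current symbol and 388 by an older synonym in a RefSeq gene table of assembly GRCr8, and 19226 kept the name in the file. Each gene was taken from its probe with the highest mean signal, which left 22104 genes, 11821 with a symbol, and 3616 of these genes had further kept probes. Where a further probe of a named gene lay over 0.5 (log2) from the printed change, its value is printed too.

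All 9 arrays entered 1 limma fit of group means, with lmFit and eBayes (limma 3.58.1, R 4.3.3), with 6 residual and 2.30 prior degrees of freedom. Tests were two-sided and a gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Where a gene was not well above background on any array of the dimmer group, its change is given as N-fold. It is the brighter group's mean over the dimmer one, floored on each array at the lowest signal well above background. For Ccl3 and Ccl19 the probe's own signal lay above that floor, so their fold is an estimate and no lower bound. Of 26 gene lists, 25 had enough measured members and were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, with an estimated correlation and fry as alternatives. Counts per list are over all genes tested and, separately, adjusted over the list alone. The number of arrays limits the precision: with 3 per group and 200 changed genes simulated, most 1.5-fold changes went undetected.

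The groups, lists, tests, named-gene rule and most alternatives were fixed before the data were examined. The rule named, per comparison, the 10 largest increases and 10 largest decreases among passing genes with a symbol and groups that do not overlap, up to 4 members of each list with the smallest adjusted p, a fixed set of 22 genes of hypoxia, proliferation, contraction and flavonoid response whether or not they passed, and 10 genes changed back. Of the fixed set, Cyp1a1 was not well above background in any group and no probe bore the name Acta2, so neither was tested. The text names part of what the rule allows, and some genes it allows are not reported here. Genes changed back are those that passed in hypoxia against normoxia and in quercetin against hypoxia in opposite directions. As both use the same hypoxia arrays, unchanged groups were simulated 100 times.

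On simulated data with 200 of 22104 genes changed, the fit recovered 26.9%, 67.2% and 95.5% of 1.5-, 2- and 4-fold changes for hypoxia against normoxia, with 3.08% of calls false. For quercetin against hypoxia it recovered 28.4%, 76.1% and 92.4% with 5.07% false, and for quercetin against normoxia 26.9%, 76.1% and 86.4% with 5.26% false. None of the 25 lists was called in any of these. The simulated noise was independent between genes, so this does not show how the list test behaves with correlated genes. In the data 44.3% to 64.2% of genes passed, so the recovered shares need not hold there.

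Alternatives chosen in advance were normexp background correction with offset 50, median scaling, quantile normalization, the deposited value table, other filters, marked spots kept, the mean over probes, array weights, a trended robust variance, fits of the 6 arrays compared, other thresholds, slide and replicate number as blocks, other set tests and leaving out each array. Scaling to spike-ins, removing the GC trend, scan day as a block and leaving out pairs of arrays were added after seeing the data.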

Results

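Pulmonary arterial smooth muscle cells (PASMCs), the contractile cells of the wall of lung arteries, were taken from male Sprague Dawley rats and profiled in culture generation 4. The cells were kept in normoxia, placed in hypoxia under 1% oxygen, or placed in hypoxia and treated with quercetin, a plant flavonol. Treatment lasted 24 h. Each of the 3 groups had 3 arrays, and total RNA was hybridised in 1 colour to Agilent whole-genome rat expression arrays. The series title and design pose 3 comparisons: what hypoxia changed, what quercetin changed in hypoxic cells, and how far quercetin-treated hypoxic cells lay from normoxic ones. Of 41012 non-control probes, 26669 were well above background on every array of at least 1 group, which gave 22104 genes for testing. Changes are log2 differences between group means ± standard error with 3 arrays per group, and each p is limma's moderated p after Benjamini-Hochberg adjustment.

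The share of probes well above background ranged from 65.1% to 74.4% in normoxia, from 53.1% to 66.7% in hypoxia and from 54.0% to 68.7% with quercetin. No spot was saturated and no pair of arrays held identical values. Across genes, arrays of 1 group correlated at 0.985 to 0.996 in normoxia, 0.996 to 0.998 in hypoxia and 0.991 to 0.997 with quercetin. The first principal component took 52.7% of the variance and set the hypoxia arrays apart from the other 6, and the second took 29.6% and parted normoxia from quercetin treatment. Normoxia replicates 1 and 2 shared a slide scanned on an earlier day, normoxia replicate 3 shared a slide with all 3 hypoxia arrays, and the 3 quercetin arrays filled a slide of their own. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Directions are relative to the 75th percentile of each array. Scaled to 6 labelling spike-in probes instead, a choice made after seeing the data, the median of all genes moved from 0.10 to -0.40 for hypoxia against normoxia and from 0.04 to -0.36 for quercetin against normoxia.

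Hypoxia raised genes that the hypoxia-inducible factors (HIF) control. Of 32 measured HIF target genes outside glycolysis, 25 rose, 1 fell and 6 did not pass, with a median change of 1.54 and the same counts adjusted over the list alone (camera adjusted p = 2.1e-04, and adjusted p = 0.66 with an estimated correlation between genes). Car9, a carbonic anhydrase, rose by 2.63 ± 0.35 (adjusted p = 2.9e-04), Stc2, a secreted stanniocalcin, by 2.22 ± 0.18 (2.3e-05), and P4ha2, a collagen prolyl hydroxylase, by 1.89 ± 0.19 (6.0e-05). Hif1a itself fell by 0.67 ± 0.12 (0.0014). Glycolysis genes rose together, with 21 of 23 members higher and none lower, and 21 adjusted over the list alone (median 1.58, camera adjusted p = 2.9e-05, and 0.66 with an estimated correlation). Pgk1 rose by 2.43 ± 0.31, Ldha by 1.80 ± 0.32 and Gapdh, often used as a reference gene, by 1.58 ± 0.14. Normoxia replicate 2 stood apart in these groups: its HIF list median was 1.42 below the mean of the other normoxia arrays and its glycolysis median 1.18 below. With slide as a block, which compares the hypoxia arrays with normoxia replicate 3 alone, the medians were 1.09 for HIF targets (adjusted p = 0.0024) and 1.23 for glycolysis (2.2e-04). Slc2a1, Pdk1, Bnip3 and Vegfa, which rose by 2.17, 2.17, 1.74 and 1.00 over all arrays, then changed by 1.51, 1.48, 1.12 and 0.67 and no longer passed (adjusted p = 0.075, 0.072, 0.15 and 0.11). Adm and Hmox1 changed by 1.08 (0.080) and 0.75 (0.26), and without normoxia replicate 3 Adm passed (1.42, 0.041). With slide as a block they changed by 0.41 (0.63) and 0.04 (0.97).

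Cell cycle genes mostly fell in hypoxia. In the mitosis list 28 of 36 genes were lower and none higher, and 28 adjusted over the list alone (median -0.88, camera adjusted p = 1.0e-07). That adjusted p was 0.66 with an estimated correlation, and with slide as a block the median was -0.98 (adjusted p = 2.7e-09). Kif20a, a kinesin of cytokinesis, fell by 1.32 ± 0.09 (adjusted p = 1.1e-05), the checkpoint kinase gene Bub1b by 1.37 ± 0.13 (5.1e-05) and the proliferation marker Mki67 by 0.82 ± 0.10 (1.6e-04). Of 39 genes of DNA replication and G1/S entry, 25 fell and 5 rose, or 26 and 5 adjusted over the list alone (median -0.69, camera adjusted p = 2.2e-04). Its adjusted p with an estimated correlation was also 0.66, and with slide as a block the median was -0.48 (0.0059). Orc1, a subunit of the origin recognition complex, fell by 3.22 ± 0.16 and the cyclin gene Ccne1 by 2.10 ± 0.17, while Ccne2 rose by 1.93 ± 0.12.

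Inflammatory genes fell as well. Of 35 cytokine, chemokine and adhesion genes, 22 fell and 5 rose, also adjusted over the list alone (median -1.42, camera adjusted p = 9.3e-04). The adjusted p was 0.66 with an estimated correlation, and the median -1.06 with slide as a block (0.0077). Tlr2, a receptor for bacterial lipopeptides, fell by 5.64 ± 0.39 (adjusted p = 1.1e-05), the metalloproteinase gene Mmp3 by 5.28 ± 0.85 (8.5e-04) and Tlr4 by 1.84 ± 0.17 (4.4e-05). Ccl3 was 30.6-fold lower by its measured signal (7.2e-06), which was not well above background on any hypoxia array, so the size is uncertain. Beside these stood Pla2g2a, a secreted phospholipase, which fell by 4.66 ± 0.37 and Epyc, a cartilage proteoglycan, by 5.28 ± 0.22.

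Smooth muscle contractile genes were mostly higher, with 14 of 26 higher and 4 lower, or 14 and 5 adjusted over the list alone. The list's median change of 0.48 did not pass (camera adjusted p = 0.13), but it did without normoxia replicate 2 (0.67, adjusted p = 0.027), and with slide as a block its median was 0.61 (0.076). The filament gene Des rose by 3.39 ± 0.16 (2.6e-06) and Cnn1, calponin, by 1.33 ± 0.13 (4.8e-05). Extracellular matrix genes went both ways, with 27 of 47 higher and 13 lower (camera adjusted p = 0.22), from Col18a1 at 1.57 ± 0.12 to the small proteoglycan Lum at -3.62 ± 0.28. Gucy1a1 and Gucy1b1, the subunits of the nitric oxide receptor soluble guanylate cyclase, fell by 3.88 ± 0.25 and 2.56 ± 0.15, and another probe of Gucy1a1 fell by 2.83. Nqo1, a quinone reductase induced by NRF2, fell by 1.29 ± 0.10 (1.7e-05). Markers of other cell types moved as well: among 9 epithelial markers 4 rose and none fell, with Krt18 at 4.93 ± 0.51 and Krt7 at 3.12 ± 0.17, and among 12 leukocyte markers 8 rose and 1 fell, with Lyz2 at 4.10 ± 0.37, although neither list passed (camera adjusted p = 0.23 and 0.21). Of 10 fibroblast markers 3 rose and 4 fell (median -0.08, camera adjusted p = 0.37), with Dcn at -4.24 ± 0.46 and Fap at -1.45 ± 0.11 beside Lum. Of 6 endothelial markers 3 rose and 1 fell (0.58). Adjusted over the list alone, the marker counts were the same, apart from 4 endothelial markers higher.

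Over all genes, 14186 passed at an adjusted p under 0.05, with 7799 higher and 6387 lower, and 5323 of them changed at least 2-fold, 2489 higher and 2834 lower. The 3 arrays of each group did not overlap for 71.7% of genes, against 10% by chance. With slide as a block 9740 genes passed, among them every gene named above as changed in hypoxia apart from Slc2a1, Pdk1, Bnip3 and Vegfa, and with normexp background correction 6704. Scaled to the spike-ins the split became 2668 higher and 10793 lower, against 7799 and 6387. None of the 5 list calls held with an estimated correlation.

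**Figure D1:**
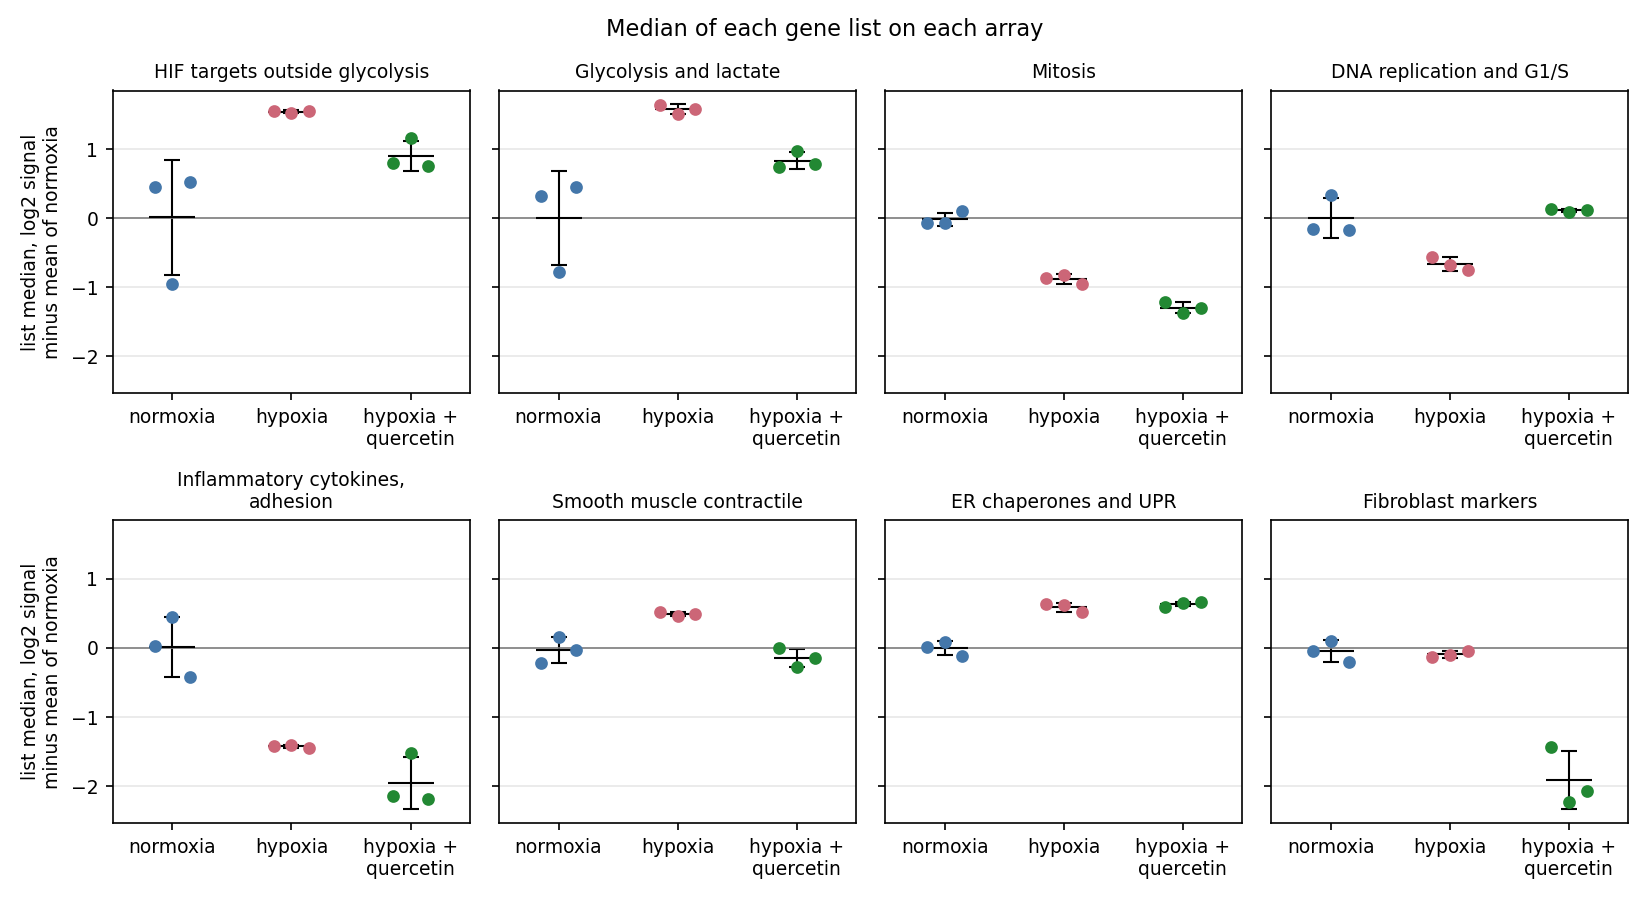
Median of 8 gene lists on each array, as log2 signal relative to the 75th percentile of the array minus each gene's normoxia mean, with points for arrays and bars for the group mean ± SD of 3 arrays. Normoxia replicate 2 lay at -0.95 in HIF targets while the other normoxia arrays lay at 0.46 and 0.52.

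Quercetin in hypoxic cells moved genes of DNA replication and of mitosis in opposite directions. DNA replication and G1/S genes rose, with 27 of 39 higher and 3 lower, or 27 and 4 adjusted over the list alone (median 0.92, camera adjusted p = 4.4e-05, and 0.81 with an estimated correlation). Orc1 rose by 3.04 ± 0.16 (adjusted p = 4.8e-06), Ccne1 by 2.64 ± 0.17 (9.7e-06) and the chromatin assembly genes Chaf1b and Chaf1a by 2.02 ± 0.14 and 1.82 ± 0.14. Mitosis genes fell further, with 19 of 36 lower and 3 higher, the same adjusted over the list alone (median -0.32, camera adjusted p = 0.011, and 0.81 with an estimated correlation). Ube2c, which serves the anaphase-promoting complex, fell by 1.55 ± 0.13 (2.9e-05), Kif23 by 1.16 ± 0.10 and Kif20a by 1.14 ± 0.09. The brighter probe of Ccnb1, cyclin B1, fell by 1.96 ± 0.12, but its other probe differed by only -0.21. Mki67 fell by 0.45 (0.0043), which did not pass with normexp background correction (0.054).

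Glycolysis genes fell, with 14 of 23 lower and none higher, the same adjusted over the list alone (median -0.79, camera adjusted p = 0.0075, and 0.81 with an estimated correlation). Aldoc, an aldolase, fell by 2.11 ± 0.35 (adjusted p = 0.0011), Pgk1 by 1.49 ± 0.31 (0.0039), Pfkm by 1.28 ± 0.09 (1.5e-05) and Gapdh by 0.77 ± 0.14 (0.0017). HIF targets outside glycolysis were less uniform: 12 of 32 fell and 3 rose, the same adjusted over the list alone, and the median of -0.66 did not pass (camera adjusted p = 0.10), but passed without normoxia replicate 2 (0.0021) or with normexp background correction (0.0039). Stc2 fell by 2.58 ± 0.18 and Pdk1 by 1.62 ± 0.45 (0.014), while Bnip3l rose by 1.56 ± 0.10. Car9 fell by 1.03 ± 0.35 (0.032), a call lost when any single hypoxia or quercetin array was left out (0.066 to 0.079). Slc2a1, Vegfa, Bnip3 and Hif1a changed by -0.51, -0.26, -0.23 and -0.05 (adjusted p = 0.36, 0.36, 0.67 and 0.74), and without normoxia replicate 2 Slc2a1 and Bnip3 passed at the same sizes (0.0080 and 0.043).

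Smooth muscle contractile genes fell, with 15 of 26 lower and 2 higher, the same adjusted over the list alone (median -0.57, camera adjusted p = 0.020, and 0.81 with an estimated correlation). Cnn1 fell by 2.50 ± 0.13 (adjusted p = 4.7e-06), Tagln, transgelin, by 1.68 ± 0.15 (4.7e-05) and Myh11, smooth muscle myosin heavy chain, by 1.45 ± 0.16 (1.2e-04) by its brighter probe and by 0.69 by the other, while the intermediate filament gene Synm rose by 1.59 ± 0.14. The list's call was lost without quercetin replicate 2 (median -0.51, 0.075), under quantile normalization (-0.31, 0.062) and for genes with signal on all 9 arrays (-0.56, 0.052). Of 47 extracellular matrix genes 26 fell and 2 rose, or 27 and 2 adjusted over the list alone (median -0.41, camera adjusted p = 0.0018, and 0.58 with an estimated correlation). Mmp9, a gelatinase, fell by 3.48 ± 0.29, Fmod by 1.85 ± 0.10 and Col6a1 by 1.60 ± 0.15. This call was lost under quantile normalization (-0.05, 0.29). Fibroblast markers fell with them, 8 of 10 lower and none higher, the same adjusted over the list alone (median -1.31, camera adjusted p = 0.011, and 0.47 with an estimated correlation), led by Fap at -2.28 ± 0.11 and S100a4 at -1.84 ± 0.25, with a further S100a4 probe at -1.26. Epithelial Krt18 and Krt7, which had risen in hypoxia, fell by 3.22 ± 0.51 and 2.39 ± 0.17. Of 9 epithelial markers 3 fell and none rose, and of 6 endothelial markers 3 fell and 1 rose, the same adjusted over the list alone. Neither list passed (median -0.50, camera adjusted p = 0.15, and -0.16, 0.77).

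Inflammatory genes were lower still, with 19 of 35 lower and 2 higher, or 19 and 3 adjusted over the list alone (median -0.97, camera adjusted p = 0.012, and 0.81 with an estimated correlation). Vcam1, an adhesion molecule for leukocytes, fell by 3.68 ± 0.22 (adjusted p = 8.9e-06), the chemokine gene Ccl5 by 3.34 ± 0.36 (1.2e-04) and Icam1 by 1.19 ± 0.12 (8.4e-05). The list's call was lost for genes with signal on all 9 arrays (median -0.95, 0.052). Of 12 leukocyte markers, which had mostly been higher in hypoxia, 6 fell and 1 rose, the same adjusted over the list alone, with Cd74 at -1.56 ± 0.13, and the list did not pass (median -0.48, camera adjusted p = 0.30). Ccl19 was 60.8-fold lower by its measured signal (1.8e-05), which was not well above background on any quercetin array, so the size is uncertain. Interferon response genes fell in 10 of 22 cases and rose in none, or 9 and none adjusted over the list alone (median -0.47, camera adjusted p = 0.049, and 0.47 with an estimated correlation). The immunoproteasome genes Psmb8 and Psmb9 fell by 3.03 ± 0.16 and 2.15 ± 0.10. That list's call was lost without normoxia replicate 1 (0.060), hypoxia replicate 2 (0.050) or quercetin replicates 1 (0.083), 2 (0.066) or 3 (0.053). It was also lost with median scaling (-0.49, 0.055), for genes with signal on all 9 arrays (-0.47, 0.052) and with normexp background correction, where the median was 0.02 (0.080). Outside these groups Enpp2, which makes lysophosphatidic acid, fell by 5.35 ± 0.30 and Lamb3, a laminin chain, by 5.05 ± 0.10, with a further Lamb3 probe at -4.11. Nqo1 rose by 1.47 ± 0.10 (1.2e-05), while of 30 NRF2 targets 11 rose and 6 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.20).

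In all, 12904 genes passed between quercetin-treated and untreated hypoxic cells, with 5935 higher and 6969 lower, of which 4559 changed at least 2-fold, 2370 higher and 2189 lower. Scaled to the spike-ins, 6495 were higher and 5645 lower. The arrays of the pair of groups did not overlap for 71.1% of genes, against 10% by chance. With normexp background correction 6148 genes passed, and no slide held both groups, so slide and quercetin cannot be told apart. None of the 8 list calls held with an estimated correlation.

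**Figure D2:**
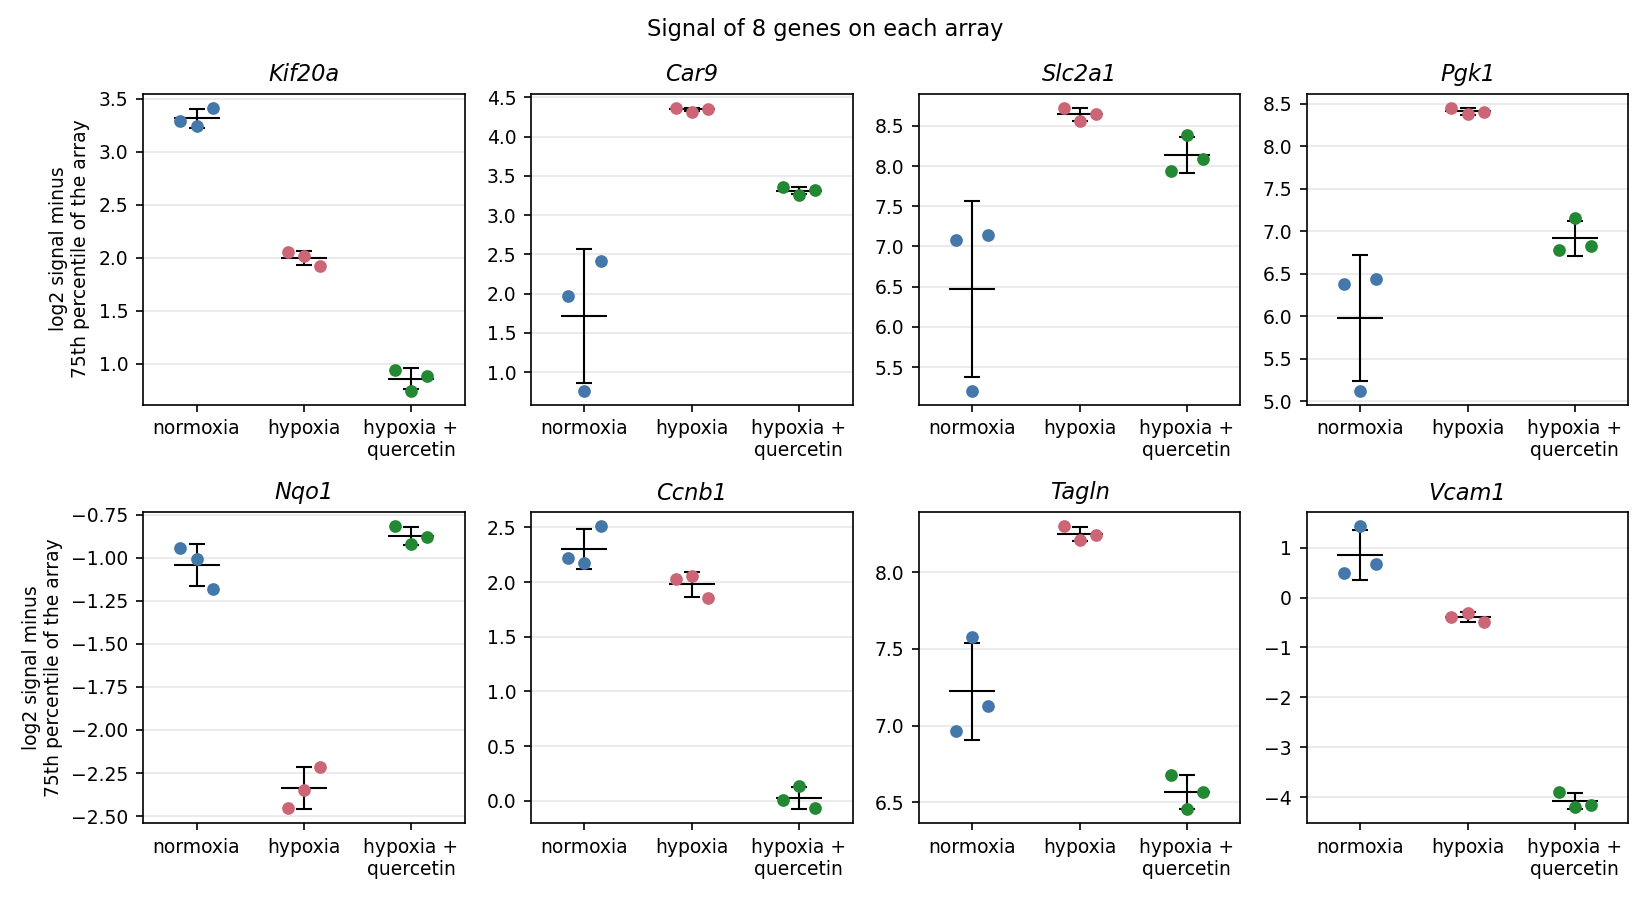
Signal of 8 genes on each array, as log2 signal minus the 75th percentile of the array, with points for arrays and bars for the group mean ± SD of 3 arrays. Slc2a1 lay between 8.56 and 8.72 in hypoxia and between 7.94 and 8.38 with quercetin, while normoxia replicate 2, at 5.21, lay below the other normoxia arrays at 7.08 and 7.14.

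Set against normoxia, cells given hypoxia and quercetin together had lower mitosis genes, with 32 of 36 lower and 1 higher, the same adjusted over the list alone (median -1.29, camera adjusted p = 1.9e-14, and 0.17 with an estimated correlation). Kif20a fell by 2.46 ± 0.09 (adjusted p = 2.7e-06), Cdc20 by 1.92 ± 0.11 (1.1e-05) and Mki67 by 1.27 ± 0.10 (4.1e-05). Inflammatory genes were lower in 27 of 35 cases and higher in none, the same adjusted over the list alone (median -2.06, camera adjusted p = 2.7e-11, and 0.26 with an estimated correlation). Tlr2 fell by 6.15 ± 0.39 (2.0e-05), Vcam1 by 4.93 ± 0.22 (6.0e-06) and Ccl5 by 4.79 ± 0.36 (3.7e-05). Interferon genes fell in 13 of 22 cases and rose in 2, or 15 and 2 adjusted over the list alone (median -0.65, camera adjusted p = 1.7e-04, and 0.062 with an estimated correlation), with Ifit2 down at -3.60 ± 0.22. Of 10 fibroblast markers 9 fell and none rose, also adjusted over the list alone (median -1.92, camera adjusted p = 8.7e-06, and 0.062 with an estimated correlation), and Fap fell by 3.73 ± 0.11. The other marker lists did not pass (camera adjusted p = 0.40 for leukocyte, 0.62 for epithelial and 0.64 for endothelial). Of 12 leukocyte markers 5 rose and 2 fell, of 9 epithelial 3 and 2, and of 6 endothelial 1 and 1, the same adjusted over the list alone. Scan day as a block, an alternative added after seeing the data, leaves normoxia replicate 3 as the only reference. The medians were then -1.45 for mitosis, -1.43 for inflammatory, -0.70 for interferon and -1.60 for fibroblast genes. No slide held both normoxia and quercetin arrays, so this block does not separate slide from quercetin.

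Chaperones of the endoplasmic reticulum rose, with 16 of 23 higher and 1 lower, the same adjusted over the list alone (median 0.62, camera adjusted p = 7.9e-06, and 0.27 with an estimated correlation). Derl3, of ER-associated degradation, rose by 4.78 ± 0.17 (adjusted p = 1.9e-06), Sdf2l1 by 1.70 ± 0.12 (2.8e-05) and the chaperone gene Hsp90b1 by 1.20 ± 0.09 (3.4e-05). ATF4 targets fell in 12 of 30 cases and rose in none, the same adjusted over the list alone (median -0.38, camera adjusted p = 0.0011, and 0.43 with an estimated correlation), with the amino acid transporter gene Slc7a5 down at -1.98 ± 0.15. With scan day as a block the medians were 0.70 for chaperones and -0.41 for ATF4 targets (adjusted p = 1.9e-08 and 0.019). Of 54 growth factor, receptor and channel genes studied in pulmonary hypertension, 12 rose and 18 fell, or 14 and 18 adjusted over the list alone, and the list did not pass (median 0.09, camera adjusted p = 0.41, with the test pointing down). Among its members Ednra, the endothelin receptor, fell by 3.21 ± 0.16 by its brighter probe and by 0.99 by the other, and the angiotensin receptor gene Agtr1a fell by 2.40 ± 0.13. Nqo1 and Ccnd1 differed from normoxia by 0.17 (0.19) and -0.21 (0.59).

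HIF targets outside glycolysis lay above normoxia in 15 of 32 cases and below in 1, and glycolysis genes in 15 of 23 and 1, or 15 and 1 and then 16 and 2 adjusted over the list alone. Their medians were 0.87 (camera adjusted p = 0.0014) and 0.81 (0.0048), with an adjusted p of 0.79 for both with an estimated correlation, and normoxia replicate 2 was again the lowest array in both lists. With scan day as a block the medians were 0.39 (0.068) and 0.43 (0.12). Car9 was 1.59 ± 0.35 higher (adjusted p = 0.0066) over all arrays and 0.89 (0.12) with that block. Slc2a1, Bnip3 and Vegfa, at 1.66, 1.51 and 0.74 over all arrays, did not pass with that block (0.25, 0.29 and 0.35) or without quercetin replicate 2 (0.057, 0.061 and 0.093), and Bnip3 and Vegfa did not without quercetin replicate 3 (0.065 for both). Nuclear genes of the respiratory chain fell in 21 of 55 cases and rose in 3, also adjusted over the list alone (median -0.17, camera adjusted p = 0.018, and 0.80 with an estimated correlation), but not without normoxia replicate 2 (-0.11, 0.23) or with that block (-0.04, 0.77).

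Between these groups 9785 genes passed, with 5080 higher and 4705 lower, 2859 of them at least 2-fold, 1259 higher and 1600 lower, and the arrays did not overlap for 53.5% of genes against 10% by chance. With scan day as a block 5809 genes passed and with normexp background correction 3165, and scaled to the spike-ins the split was 1671 higher and 9786 lower. None of the 9 list calls held with an estimated correlation.

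Of the 14186 genes that hypoxia changed, 63.6% moved back with quercetin, and with a 2-fold change required in both comparisons 2531 of 5323 did. Of 9864 genes that passed both in hypoxia against normoxia and with quercetin against hypoxia, 9025 went in opposite directions, 4889 raised by hypoxia and lowered by quercetin and 4136 lowered and then raised. Lamb3 rose by 4.33 ± 0.10 in hypoxia and fell by 5.05 ± 0.10 with quercetin, or by 3.48 and then -4.11 at the probe farthest from these. Il1rap, the accessory protein of the interleukin-1 receptor, rose by 3.33 ± 0.10 and fell by 2.73 ± 0.10, and Tcea3, an elongation factor gene, rose by 2.37 ± 0.10 and fell by 2.94 ± 0.10. In the other direction, Dph3, needed for diphthamide synthesis, fell by 4.00 ± 0.11 and rose by 2.86 ± 0.11, Heatr1 of ribosome biogenesis fell by 3.71 ± 0.12 and rose by 2.89 ± 0.12, and Ciapin1 fell by 3.30 ± 0.11 and rose by 3.11 ± 0.11. The brighter probe of the chaperone gene Hspa4 fell by 3.87 ± 0.14 and rose by 4.04 ± 0.14, while its other probe changed by 0.07 and 0.37. Dph3, Heatr1 and Ciapin1, like Il1rap and Tcea3, had only 1 kept probe each, so no further probe could check them. Of the 9025 genes, 5667 did not pass between quercetin and normoxia, which does not show that they were equal.

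Both comparisons use the same hypoxia arrays with opposite sign, so some opposite movement is built in. Unchanged groups simulated 100 times against shared arrays gave 0.01 opposite calls on average. As no gene differed there, almost none could pass, so this count does not measure what sharing adds among genes that differ. Independent lists of these sizes would share 4174 genes in opposite directions, 2459 raised then lowered and 1715 lowered then raised. Across genes, which are not independent replicates, the fold changes correlated at -0.67 against a simulated -0.50, and their covariance was -0.601 against a simulated -0.030, a difference of -0.570. The 3 hypoxia arrays were too few for parts of at least 2 each, so part of the excess of opposite calls over independent lists may come from sharing them. With normexp background correction, where fewer genes passed in each comparison, 3917 genes went in opposite directions. The 4174 above holds for the longer main lists and is no measure for that count. No slide held both hypoxia and quercetin arrays.

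**Figure D3:**
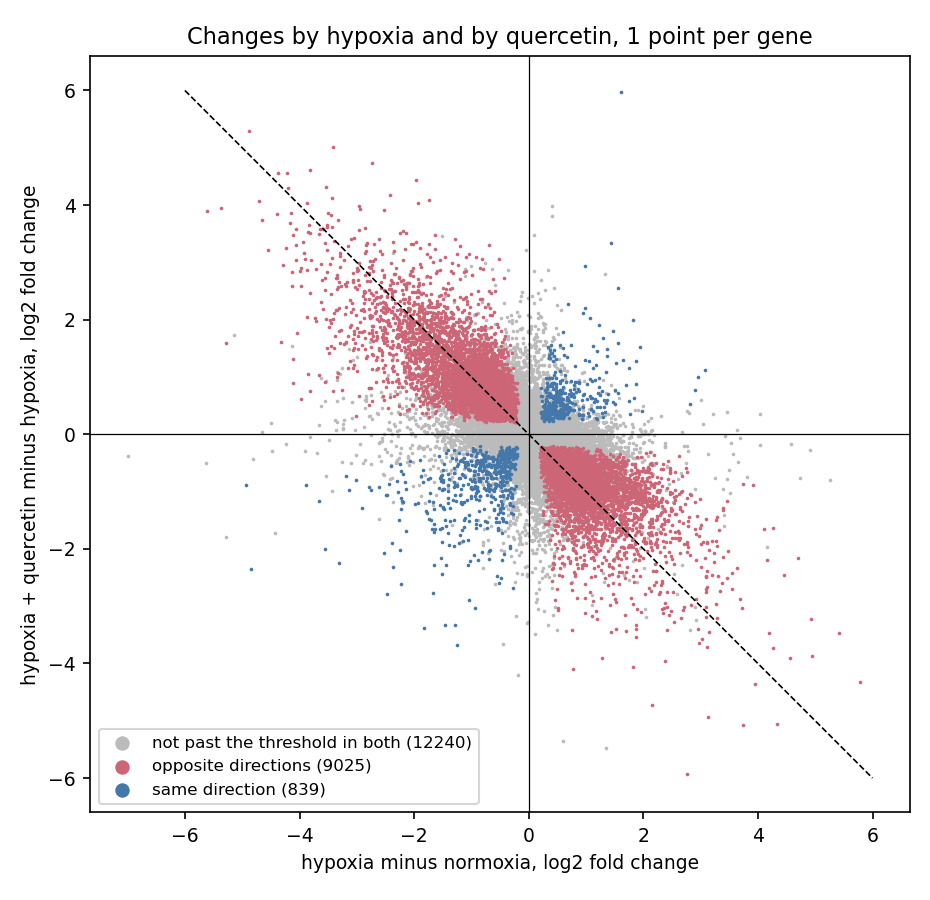
Log2 change with quercetin in hypoxia against log2 change by hypoxia, 1 point per gene, with the dashed line where quercetin would undo the hypoxia change exactly. Points in red, 9025 genes, passed both tests in opposite directions, points in blue, 839 genes, in the same direction, and grey points did not pass both.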

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

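Of the tests in this part, the share of RT1 genes, the cell type markers, the slope for the slide of the hypoxia arrays and the splits were fixed before their results were seen. The other tests and the spike-in measurement were chosen after seeing the data. Control probes outside the comparisons stood differently against the genes in each group: the 6 labelling spike-in probes, relative to the 75th percentile of each array, were 0.505 higher in hypoxia and 0.403 higher with quercetin than in normoxia (log2; means 6.46 ± 0.02, 6.35 ± 0.12 and 5.95 ± 0.02, SD of 3 arrays). Before scaling their mean log2 signal was 15.14 to 15.22 on all 9 arrays, so the difference lies in the 75th percentile of the genes.

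Genes moved by hypoxia moved back with quercetin, 9025 of them. Sharing of the hypoxia arrays, with noise as between arrays of a group, cannot account for this as a whole. The covariance was -0.601 against -0.030 simulated with such noise. A deviation common to all 3 hypoxia arrays was not simulated and stays open. Probe GC content cannot account for the moves as a whole either, since 8770 genes still moved back with its trend removed. A difference of the slide that holds the hypoxia arrays would place normoxia replicate 3, on the same slide, near hypoxia. Its slope on the hypoxia-minus-quercetin difference was 0.097, far below the 0.5 set in advance for such a difference. That was only just under the lower limit, also set in advance, for arguing against one. The other normoxia arrays gave -0.025 and -0.072. Each array was set against the others, so the slopes are tied and give no independent reference. By this 1 array, at most a small part may come from that slide. Whether the slide of the quercetin arrays contributes cannot be told apart from quercetin itself, because it holds only that group, and the 8565 genes called with slide as a random block do not decide it. Of 100 drawn splits of the 9 arrays, only 1, the real one, had as many genes changed back (9025, highest other 6619). A covariance as far below 0 came from 2 (-0.601, and 1 other split, farther, at -0.727). A random division of these arrays thus rarely gave such values. Only 1 other drawn split kept the real groups, so the splits show that groups differ and not that quercetin undoes hypoxia. Chance differences between single cultures and a response to quercetin both stay open.

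Normoxia replicate 2 lay below the other normoxia arrays in HIF targets by 1.42. Brightness or scaling of the array is excluded, because its inflammatory list lay 2.09 above its HIF list by the same measure, and so is slide or scan day, because normoxia replicate 1, on the same slide, differed from replicate 3 by only -0.0964. RNA of other cell types is argued against by marker lists of endothelial, leukocyte, epithelial and fibroblast cells, the highest of which moved by 0.156. No biological explanation was tested, as the labels give none within a group, and a difference in the culture of that sample stays open.

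Some genes lost 1 probe's signal while another probe of the gene hardly moved, such as Hspa4 in hypoxia (-3.87 and 0.07). Of genes with a probe changed by at least 3 (log2), 7 of 44 had another within 0.5 for hypoxia against normoxia, all 7 lower in hypoxia, 4 of 31 for quercetin against hypoxia and 5 of 28 for quercetin against normoxia. A candidate explanation is a sequence variant under a probe between groups of cells from different rats. Genes of RT1, the polymorphic histocompatibility region, would then often change strongly: 3 of 26 changed by over 2 for quercetin against normoxia, at percentile 99.26 of matched random lists, while for hypoxia against normoxia the percentile was 94.8 and for quercetin against hypoxia 62.1. Real regulation of RT1 genes would give the same, and whether groups came from different rats is not given in the sources used here. The highest of the 3 percentiles came from quercetin against normoxia, where the Hspa4 probes differed by only 0.17 and 0.44. It therefore does not decide what caused the losses in hypoxia.

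The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. For genes changed 1 of 10, the real one, reached the real value in each comparison (14186, 12904 and 9785, highest other 0, 0 and 3). For lists the numbers were 7 of 10 for hypoxia against normoxia (real 5, highest other 8), 1 for quercetin against hypoxia (8, highest other 5) and 6 for quercetin against normoxia (9, highest other 12). In hypoxia against normoxia and in quercetin against normoxia, most splits thus gave at least as many list calls as the real one. There the number of list calls does not set the real groups apart from mixed ones.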

How the results depend on the processing

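Of the settings in this part, spike-in scaling, the GC trend, scan day and both settings that leave out a pair of arrays were chosen after seeing the data. Over all settings but the other set tests, 6360 of 6598 single-gene values and 2075 of 2150 list values kept direction and side of the threshold. The threshold was lost in 211 and 28 and gained in 22 and 47. Estimated correlation and fry are not in these counts, and with the former no list call held. The 5 reversals, all from values that did not pass at first, were Cdkn1a with quercetin against hypoxia (-0.08 to 0.43 under quantile normalization and 0.42 in the deposited value table) and, with normoxia and quercetin replicates 2 left out together, Hmox1 against hypoxia (0.05 to -0.34) and normoxia (0.80 to -0.28) and Adm against normoxia (0.56 to -0.33). The cause was not tested unless stated.

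Normexp background correction gave 6704, 6148 and 3165 genes in hypoxia against normoxia, quercetin against hypoxia and quercetin against normoxia, 8 lists for the first, 3917 genes changed back and a covariance of -0.28. Requiring 2-fold gave 5323, 4559, 2859 and 2531 changed back, by construction, and 2-fold with unadjusted p gave 5366, 4628, 2934 and 2573. At an adjusted p of 0.01, 6408 genes passed for quercetin against normoxia and 3 lists for quercetin against hypoxia. With scan day as a block 5809 genes passed for quercetin against normoxia, with 1 normoxia array on that day. Requiring signal on all 9 arrays left 5 lists for quercetin against hypoxia. Estimated correlation left 0, 0 and 0 lists, while fry, which does not compare a list with other genes, called 21, 20 and 15. The covariance was -0.6215 under quantile normalization, -0.6217 in the value table, -0.52 with no filter, -0.46 with signal on all arrays, -0.55 with scan day, -0.58 without the GC trend, -0.63 without hypoxia replicate 3 and quercetin replicate 1 and -0.5834 without normoxia and quercetin replicates 2. Leaving out each array in turn gave 12323 to 14403, 10984 to 14024 and 7687 to 9870 genes, 5 to 7, 6 to 9 and 9 to 10 lists, 7366 to 9381 changed back and a covariance of -0.64 to -0.58.

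With replicate number as a block 13195, 11967 and 8496 genes passed, 8210 changed back and 5, 8 and 9 lists. Same-numbered arrays deviated from their group means with correlations of -0.27 to 0.02 across genes. No pairing by number was visible, which does not show that samples were unpaired. Dim probes limit the rest: down to 53.1% of probes were well above background on an array.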

Other observations

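Lipid synthesis genes split in hypoxia and with quercetin. Of 29 genes of cholesterol synthesis and uptake 6 rose and 13 fell in hypoxia, and 11 rose and 10 fell with quercetin against hypoxia, the same adjusted over the list alone (camera adjusted p = 0.25 and 0.51, the second with a median of -0.13 and the test pointing up). Fasn, fatty acid synthase, fell by 1.89 ± 0.09 in hypoxia and rose by 1.93 ± 0.09 with quercetin. With quercetin Sqle rose by 1.86 ± 0.12 and Acat2 by 2.17 ± 0.15.

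Among vascular genes, Pparg, a nuclear receptor, fell by 1.89 ± 0.12 in hypoxia, although with normexp background correction the change was -0.43 and did not pass (adjusted p = 0.55). Notch4 rose by 4.56 ± 0.38 in hypoxia, and Jag2, a Notch ligand, was 4.39 ± 0.19 higher with quercetin than in normoxia. With quercetin against hypoxia the prostacyclin synthase gene Ptgis fell by 1.93 ± 0.10 and the potassium channel gene Kcnk2 rose by 3.61 ± 0.21. Of 23 p53 targets 11 rose and 2 fell with quercetin against hypoxia, the same adjusted over the list alone (median 0.32, camera adjusted p = 0.074), with Ddb2 up by 1.21 ± 0.17 and Ei24 by 1.11 ± 0.08, while Cdkn1a changed by -0.08 (0.53), or by 0.43 (0.0056) under quantile normalization and 0.42 (0.0061) in the deposited value table. Endoplasmic reticulum chaperones rose in 15 of 23 cases and fell in 5 in hypoxia, also adjusted over the list alone (median 0.60, camera adjusted p = 0.073), and passed without normoxia replicate 2 (0.029) and with slide as a block (0.69, 0.0096). Cyp1b1, a target of the aryl hydrocarbon receptor to which flavonoids can bind, changed by 0.33 (0.20) with quercetin against hypoxia, and of 7 such targets 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.50).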
